A study of Mus musculus with 134 samples.

How the data were processed

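Gene expression was measured on Illumina mouse bead arrays in total RNA from the ventral striatum of naive mice, dissected by hand from frozen brains, per the labels. The mice came from 3 populations. HSNPT is an outbred stock of intercrossed inbred strains, and HDID1 and HDID2 are lines bred from it in separate selections for drinking alcohol in the dark. Groups and sex were taken from the labels of the samples. The selection labels also carried a number that was the same within a line and differed between lines. Any effect of what this number stands for cannot be told apart from that of line. The series held 134 samples, and the signals of 133 arrays were used: 42 from HSNPT (19 females and 23 males), 46 from HDID1 (24 and 22) and 45 from HDID2 (25 and 20). The remaining sample carried no sex in its label, so it entered no fit with a sex term. Each line was 1 population. The p-values therefore measured the spread between mice of a line, and mice are not replicates of the selection.

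The deposited intensity values were mean bead signals per probe and array, neither background-corrected nor normalized, per the file headers. The deposited detection p-value gave, for each probe and array, how often the negative control beads were as bright as the probe, per the file headers and column names. A note in the file headers says that the authors dropped some marked samples as outliers, and the text used here carries no such marks. The authors' value table held a second set of intensity values for 134 columns. Its linear scale was inferred from the values, since each of the 133 arrays correlated best with its own column, and its column medians lay between 8.40 and 8.43 after log2. The method behind the authors' value table is not given in the sources used here, and whether a background was subtracted stays unknown. The values were not centred by gene.

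Signals were background-corrected with neqc in limma 3.58.1 under R 4.3.3. The background was inferred from the detection p-values, the offset was 16, and the arrays were quantile-normalized and put on the log2 scale. Of 25697 probes, 13027 were kept because their detection p was below 0.01 on at least 21 arrays. Names came through Entrez gene numbers for 23788 probes and through accessions for 1148 in a RefSeq gene table of assembly GRCm38.p6, and 761 kept the name in the file. Each gene was represented by its kept probe with the highest mean, which gave 9645 genes and left 3382 second probes aside. The table named 9335 of these genes. Chromosomes came from the array annotation for 8200 genes. The genome build of that annotation is not given in the sources used here, so no coordinates are printed.

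Median raw signal per array ran from 182.9 to 469.8, with a median of 341.8. The share of probes detected ran from 3.08% to 49.5%, with a median of 45.3%. Arrays were also compared by their mean Pearson correlation with all others, and 17 arrays below 0.85 were treated as standing apart. That rule was chosen after the data were examined, and each lead count is given with and without these arrays. The number of arrays limits the precision of all values.

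Each gene was fitted with limma's lmFit and eBayes, with line and sex as terms over all 3 lines, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Contrasts were each selected line against HSNPT, the mean of both against HSNPT, HDID1 against HDID2, male against female, and a test of line-by-sex terms. Errors given as SE are limma's moderated standard errors of the log2 difference. All tests were two-sided. A gene called different is one past that threshold. Where a gene was undetected on every array of a group, a bound was computed from the dimmest detected signal. No such gene had a brighter group whose mean exceeded its bound, so no lower limit of a fold is given.

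The effect of a shared control was estimated with 100 simulations of unchanged lines against the HSNPT arrays, with the overlap of independent lists, and with 20 random splits of the HSNPT arrays into a separate control for each line. The correlation between lines was resampled 100 times over arrays.

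The 31 gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists of a contrast. They covered D1 medium spiny neuron markers, D2 medium spiny neuron markers, striatal projection neuron genes, cortical excitatory neuron markers, hypothalamic markers, cholinergic neuron markers, interneuron markers, choroid plexus markers, oligodendrocyte and myelin markers, astrocyte markers, microglia markers, endothelial markers and red blood cell markers. Others were GABA-A receptor subunits, ionotropic glutamate receptors, metabotropic glutamate receptors with postsynaptic scaffolds, potassium channels, sodium and calcium channels, dopamine signalling, opioid, CRF and other neuropeptide systems, alcohol and aldehyde metabolism and neuroimmune signalling. The rest were immediate early genes, circadian clock genes, oxidative phosphorylation subunits, cytosolic ribosomal proteins, histone acetylation enzymes, cadherins and protocadherins, class I MHC genes, heat shock and chaperone genes, and sex-chromosome genes used to check labels.

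Coexpression was computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 on the 4000 genes of largest residual variance, after line and sex means were removed. Measures were the mean squared correlation, the density of modules of at least 30 genes built from topological overlap of the correlation raised to power 6, each gene's connectivity, and the ratio of within-line variances. They were set against 100 permutations of line within sex, with 0.0099 as the smallest p these can give. Called genes were counted per chromosome with Fisher's exact test. Figures were drawn with matplotlib 3.10.9, and tables were read with the data.table package (version 1.17.8).

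The scripts were tested on simulated data. For HDID1 against HSNPT over 9645 genes, with 50 changed genes per size, limma recovered 6% of changes of 0.25 on the log2 scale, 58% of changes of 0.5, 98% of changes of 1 and 100% of changes of 2, and called 0 unchanged genes. Without the 17 arrays it recovered 50%, 92%, 100% and 100%, and called 2 unchanged genes. The network measures did less well on 4000 simulated genes of which 100 lost a shared factor in HDID1. With that block as the only correlated one, scaled connectivity called 8 of the 100 changed genes and 3900 unchanged ones, unscaled connectivity called 100 of the changed and 0 of the unchanged genes, and the changed module had p = 0.0099 but an adjusted p of 0.178 over 36 modules. Unscaled connectivity also called 20 of the 100 genes in HDID2, where no factor had been removed. With another block correlated in every line, both forms called 0 changed genes, and the module was called with an adjusted p of 0.0396 over 4 modules. A count of 0 from these measures is therefore weak evidence.

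The groups, contrasts, main model, gene lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took the 8 called genes with the largest rise and the 8 with the largest fall of each line against HSNPT, up to 10 each way of those called in both lines, and 6 each way for HDID1 against HDID2 and for sex. It added the 6 lowest p-values of the interaction, up to 4 members per list by p in the mean contrast, the 5 best connected genes of a named module, and 12 genes fixed by name: Drd1, Drd2, Penk, Pdyn, Tac1, Ppp1r1b, Adora2a, Oprm1, Oprk1, Npy, Crh and Bdnf. Further called members of the striatal projection neuron list, all genes opposite in the lines, and genes of the chromosome and level descriptions outside this rule were chosen after their values were seen. Of the genes called in both lines, 1 is not reported here by name, is not drawn, and is kept in every count.

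Alternatives covered the background and normalization, the authors' value table, the detection filter, every kept probe, the letter in the sample titles as a term or as a restriction, residual principal components, array weights, only the groups compared, each sex alone, a fold threshold, the sex term, and for the network the correlation, the power and the choice of genes. Alternatives added later left out the arrays standing apart, took runs of such arrays as a term, left out arrays whose sex-chromosome transcripts went against the label, took the letter B alone, and used the value table with the sample of unlabelled sex. The slide of an array was not used, since the sources used here do not give it. The genotypes named in the series text were not analysed here.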

Results

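Expression of 9645 genes was measured in the ventral striatum of 42 HSNPT, 46 HDID1 and 45 HDID2 mice, all naive. Both selected lines were bred from the HSNPT stock by selection for drinking in the dark, and the series asked whether this selection altered gene coexpression in the brain. Median raw intensity per array was similar between the groups, at 340.6 in HSNPT, 343.2 in HDID1 and 346.2 in HDID2. The median share of probes detected was 45.4%, 45.7% and 45.2%. A set of 17 arrays stood apart, with a mean correlation with the other arrays below 0.85. They comprised a run of 7 arrays with a median of 28.2% of probes detected, a run of 8 arrays with 41.3%, HSNPT mouse 137 with 32.5% and HDID2 mouse 102 with 3.08%. They belonged to HSNPT (7 arrays), HDID1 (4) and HDID2 (6). The other 116 arrays had mean correlations of 0.873 to 0.933, and counts are given below with all arrays and again without the 17.

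**Figure D1:**
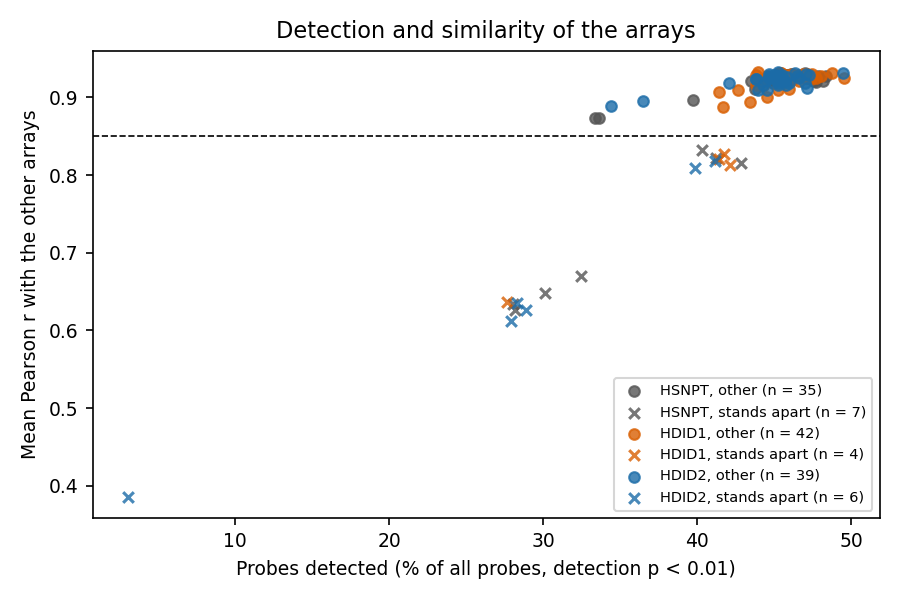
Each point is 1 of the 133 arrays, with the share of probes detected (%) on the x axis and the mean Pearson correlation with the other arrays on the y axis. Crosses mark the 17 arrays below the dashed line at 0.85, of which 7 are HSNPT, 4 HDID1 and 6 HDID2.

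The first comparison asked how the HDID1 line differed from the HSNPT stock. Among the probes that represented genes, the one with the largest fall in HDID1 was that of Tmem68, which encodes a membrane protein of lipid synthesis. Its log2 intensity was 9.68 ± 2.24 (SD, n = 42) in HSNPT and 6.99 ± 1.12 (n = 46) in HDID1, a difference of -2.69 (SE 0.325, limma adjusted p = 2.16e-10). Tomm22, a receptor for protein import into mitochondria, rose by 1.46 (SE 0.217, adjusted p = 4.62e-07) and lay above the HSNPT mean on 42 of 46 HDID1 arrays. Pgap4, an enzyme that modifies glycosylphosphatidylinositol anchors, rose by 1.17 (SE 0.104, adjusted p = 5.07e-17) and lay above that mean on 46 of 46 arrays. A second probe of Nln, named after its value was seen, fell by more than that of Tmem68 (-3.20, unadjusted p = 2.6e-28), while the probe that represented Nln had a difference of -0.39. The chemokine gene Ccl27a fell, with a difference of -1.20 (SE 0.143, adjusted p = 1.72e-10).

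Other large rises in HDID1 were those of the secreted signalling protein Wnt2 (1.41, SE 0.325), the splicing factor partner Clasrp (1.34, SE 0.203), the homeobox gene Shox2 (1.17, SE 0.328), the neuronal calcium-binding protein Necab1 (1.15, SE 0.306), 4833420G17Rik (1.14, SE 0.292) and the initiator caspase Casp9 (1.09, SE 0.284). Their limma adjusted p-values lay between 8.32e-07 for Clasrp and 0.0287 for Shox2. Other large falls were those of Mettl14, a subunit of the RNA adenosine methyltransferase (-1.22, SE 0.314), the trafficking gene Trappc13 (-1.13, SE 0.194), the translation factor gene Paip1 (-1.13, SE 0.201), the keratin Krt12 (-1.12, SE 0.292), the lipid transport gene Arv1 (-1.11, SE 0.177) and the cytosolic malic enzyme Me1 (-1.07, SE 0.325). Their adjusted p-values lay between 3.8e-06 for Arv1 and 0.0474 for Me1. Arv1 was dim, detected on 19 of 42 HSNPT, 1 of 46 HDID1 and 11 of 45 HDID2 arrays, so that the size of its fall was measured against signals near background. To a lesser degree this also holds for Tmem68, Mettl14 and Me1, each detected on 22 of 46 HDID1 arrays, and for the rise of Shox2, detected on 17 of 42 HSNPT arrays.

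In all, limma called 269 of 9645 genes different between HDID1 and HSNPT, 105 higher and 164 lower, with a median absolute log2 difference of 0.57. When the 17 arrays were left out it called 1338 genes, 689 higher and 649 lower, with a median of 0.28. These included 265 of the 269 in the same direction. The letter in the sample titles was uneven over the lines, with B on 12 of 46 HDID1, 4 of 42 HSNPT and 6 of 45 HDID2 arrays. The count was 138 with this letter as a term and 84 among arrays with the letter A. It was 3, with 741 at an unadjusted p below 0.05, among the 22 arrays with the letter B, which held 4 HSNPT arrays, all of males. Females alone gave 84 genes and males alone 16, and a term for the runs of arrays standing apart gave 1405.

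Several genes of striatal neurons were lower in HDID1. Of 13 measured striatal projection neuron genes, 6 fell, 0 rose and 7 were not called, and 10 fell when adjusted over the list alone. The members that fell were Syndig1l (-0.78, SE 0.224), the sodium channel subunit Scn4b (-0.67, SE 0.196), the dopamine-regulated phosphatase inhibitor Ppp1r1b (-0.59, SE 0.181), the transcription factor Foxp1 (-0.53, SE 0.156), Arpp21 (-0.51, SE 0.149) and the phosphodiesterase Pde1b (-0.40, SE 0.119). The phosphodiesterase Pde10a had a difference of -0.67 and an adjusted p of 0.0586. Foxp1 and Arpp21 were named after their values were seen. Other kept probes of Arpp21 had differences of -0.02 (unadjusted p = 0.885) and -0.63 (p = 0.0646). The list's median was -0.52, and camera's adjusted p was 2.67e-09, against an adjusted p = 0.120 with an estimated correlation. Leaving out the 17 arrays, 12 members fell. Over all arrays the hypothalamic markers had a median of 0.91. Their mean log2 intensity was 9.43 ± 1.47 (SD, n = 42) in HSNPT and 10.5 ± 1.56 (n = 46) in HDID1, where that of the striatal list was 12.3 ± 0.492 and 11.8 ± 0.879. The striatal mean was uneven over the HDID1 arrays, at 9.19, 9.40, 9.53, 10.09 and 10.12 in mice 1, 43, 35, 45 and 39. Their hypothalamic means were 12.29, 11.07, 12.56, 13 and 12.38. Among the other arrays that did not stand apart, HSNPT mouse 117 had 10.08, and the lowest HDID2 value was 11.18. These arrays were picked after their values were seen, and how far they carried the fall was not tested.

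Of 4 measured D2 medium spiny neuron markers, 2 fell, and 3 when adjusted over the list alone. They were the dopamine receptor Drd2 (-0.62, SE 0.186, limma adjusted p = 0.0436) and the adenosine receptor Adora2a (-0.60, SE 0.159, adjusted p = 0.0189), each below the HSNPT mean on all but 13 of 46 arrays. The list's median was -0.61 and camera's adjusted p 0.000201, against an adjusted p = 0.0894 with an estimated correlation. Of 6 D1 medium spiny neuron markers, the tachykinin precursor Tac1 fell (-0.54, SE 0.166, adjusted p = 0.0493), 5 were not called, and 2 fell when adjusted over the list alone. The dopamine receptor Drd1 had a difference of -0.55 (SE 0.2, adjusted p = 0.120) and the dynorphin precursor Pdyn one of -0.11 (adjusted p = 0.791). Their adjusted p-values without the 17 arrays were 0.0125 and 0.0123. Among 9 dopamine signalling genes, which share 6 members with other lists, 2 fell. Adjusted over the list alone, 4 were lower and 2 higher.

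Of 11 immediate early genes, which neurons transcribe after activity, 3 were called lower in HDID1. Arc (-0.99, SE 0.197, limma adjusted p = 0.000481), Egr2 (-0.92, SE 0.242, adjusted p = 0.0174) and Junb (-0.69, SE 0.181, adjusted p = 0.0163) fell, and the other 8 of 11 were not called. Adjusted over the list alone, 4 fell. The list's median was -0.29 with a camera adjusted p of 0.000145, and an adjusted p = 0.0894 with an estimated correlation. On the 116 other arrays 7 members fell, with a median of -0.55. Some ion channel genes also fell. Of 19 sodium and calcium channel genes, Scn4b, Cacng3 (-0.41, SE 0.110) and Cacna1h (-0.38, SE 0.112) fell and 16 were not called. A second probe of Cacng3 had a difference of -0.04 (unadjusted p = 0.846). Adjusted over the list alone, 5 were lower and 1 higher. Camera's adjusted p was 0.000488, against an adjusted p = 0.100 with an estimated correlation. Of 24 potassium channel genes only Kcnh3 passed over all genes (-0.89, SE 0.233), while 7 were lower and 1 higher when adjusted over the list alone. The median was -0.12 and camera's adjusted p 0.00136, against an adjusted p = 0.0894 with an estimated correlation.

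Hypothalamic markers were the list that passed camera towards higher values in HDID1. The releasing hormone precursor Trh rose (0.81, SE 0.227, limma adjusted p = 0.0282), and 4 of 6 members were higher when adjusted over the list alone. The melanin-concentrating hormone precursor Pmch had a difference of 1.94 (SE 0.626, adjusted p = 0.0677) and the galanin precursor Gal one of 1.01 (SE 0.331, adjusted p = 0.0734). Camera's adjusted p for the list was 0.000488, against an adjusted p = 0.120 with an estimated correlation.

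Lists not past the set test in HDID1 still held called members. The microglial receptor Trem2 fell (-0.38, SE 0.0872) among 11 microglia markers, the clock factor Npas2 (-0.63, SE 0.146) among 14 circadian clock genes, the haemoglobin gene Hba-a1 (-0.48, SE 0.142) among 3 red blood cell markers and the chaperone gene Dnajb5 (-0.65, SE 0.133; detected on 7 of 46 HDID1 arrays) among 12 heat shock and chaperone genes. Each of these was also the 1 member called when adjusted over its list alone. The receptor subunit Gabra3 rose (0.44, SE 0.132), alone among 7 GABA-A receptor subunits by both adjustments. Of 19 genes of opioid, CRF and other neuropeptide systems, Tac1 and the neuropeptide Y receptor Npy1r (-0.39, SE 0.114) fell. Adjusted over the list alone, 2 were lower and 1 higher.

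In the other lists 0 members were called by limma over all genes. These were the markers of cortical excitatory neurons (7 measured, median -0.21), cholinergic neurons (6, -0.10), interneurons (8, 0.23), choroid plexus (10, 0.05), oligodendrocytes and myelin (11, 0.14), astrocytes (9, 0.04) and endothelium (7, -0.10). The same held for ionotropic glutamate receptors (9, -0.06), oxidative phosphorylation subunits (30, 0.05), cytosolic ribosomal proteins (52, 0.02), histone acetylation enzymes (19, 0.12), cadherins and protocadherins (35, 0.05), neuroimmune signalling genes (8, -0.04) and the sex-chromosome genes (9, 0.14). Adjusted over the list alone, 0 of these passed. A single member passed that way among 11 metabotropic glutamate receptors and scaffolds (lower, median -0.20), 9 class I MHC genes (lower, -0.16) and 9 alcohol and aldehyde metabolism genes (higher, 0.11). Medians and means lay above 0 while camera's direction was down for choroid plexus markers, ribosomal proteins and chaperones. In HDID1, 6 of 31 lists passed camera and 0 passed with an estimated correlation, and 7 passed fry. Fry, which asks whether a list moves 1 way on balance, also passed the interneuron markers (adjusted p = 0.00412). Of the 12 genes fixed by name, Oprk1 (0.01), Npy (-0.28), Crh (0.44) and Bdnf (-0.01) were not called, and Penk and Oprm1 were not among the genes tested.

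The second comparison set HDID2 against HSNPT. Among the probes that represented genes, the largest rise was that of Cops8, a subunit of the COP9 signalosome, at 1.54 (SE 0.315, limma adjusted p = 0.00241), and it lay above the HSNPT mean on 38 of 45 arrays. The largest fall was that of Actl6b, a neuronal subunit of a chromatin remodelling complex, at -1.47 (SE 0.198, adjusted p = 4.14e-08), while its 3 other kept probes fell by less (-0.34, -0.35 and -0.52). Its log2 intensity by the representative probe was 10.85 ± 0.894 (SD, n = 42) in HSNPT, 10.77 ± 0.499 (n = 46) in HDID1 and 9.38 ± 1.24 (n = 45) in HDID2. Rusc2 fell by 1.41 on the log2 scale (SE 0.190, adjusted p = 4.14e-08) and lay above the HSNPT mean on 2 of 45 arrays.

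Other large rises in HDID2 were those of the protease inhibitor gene Spink8 (1.43, SE 0.312), Necab1 (1.37, SE 0.309), Tmem68 (1.37, SE 0.327), Krt12 (1.28, SE 0.294), Gm5148 (1.20, SE 0.214) and the cilium gene Evc2 (1.03, SE 0.171). Cbwd1 also rose (1.32, SE 0.349). Other large falls were those of Me1 (-1.39, SE 0.327), the sulphate transporter Slc13a4 (-0.94, SE 0.231), Slc7a14 (-0.89, SE 0.233), the acyltransferase Agpat5 (-0.85, SE 0.182), the pseudogene Pisd-ps1 (-0.81, SE 0.121) and the Wnt co-receptor Lrp6 (-0.77, SE 0.169). Their adjusted p-values lay between 1.52e-06 for Pisd-ps1 and 0.0439 for Cbwd1 and Slc7a14, those of the rises included. Sizes were set against dim signals for Spink8, Cbwd1, Evc2 and Gm5148, detected on 10, 19, 18 and 20 of 42 HSNPT arrays, and for Me1, detected on 16 of 45 HDID2 arrays. Limma called 58 genes, 27 higher and 31 lower, with a median absolute log2 difference of 0.68. Without the 17 arrays it called 215, 88 higher and 127 lower, and these included 54 of the 58 in the same direction. The count was 6 among genes detected on 90% of arrays, 37 without a detection filter, 30 among arrays with the letter A, 4 among those with the letter B, 24 when only HDID2 and HSNPT were fitted, 9 in females and 8 in males. A term for the runs of arrays gave 201.

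By gene list, camera passed myelin markers towards higher values and endothelial, choroid plexus and heat shock lists towards lower values in HDID2, while 0 lists passed with an estimated correlation. The oligodendrocyte and myelin list had a median of 0.14 over 11 genes, with 0 called over all genes and 0 adjusted over the list alone. Camera's adjusted p was 7.6e-06, against an adjusted p = 0.0800 with an estimated correlation. The lipid-synthesis gene Ugt8a had a difference of 0.31 (adjusted p = 0.358). Endothelial markers had a median of -0.28 over 7 genes, 0 called and 2 lower when adjusted over the list alone. Camera's adjusted p was 0.000887, against an adjusted p = 0.0800 with an estimated correlation. The tight junction gene Cldn5 had a difference of -0.56 (adjusted p = 0.271). Choroid plexus markers had a median of -0.35 over 10 genes, with 0 called by either adjustment and an adjusted p of 0.0259, against an adjusted p = 0.687 with an estimated correlation.

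Of 12 heat shock and chaperone genes the small chaperone Hspb1 fell in HDID2 (-0.56, SE 0.135, limma adjusted p = 0.0185), and 3 were lower when adjusted over the list alone. The median was -0.09 and camera's adjusted p 0.0377, against an adjusted p = 0.336 with an estimated correlation. The CRF receptor Crhr1 (-0.53, SE 0.142, adjusted p = 0.0495) was the only one of 19 neuropeptide system genes called, by either adjustment. The class I gene H2-Q8 (-0.49, SE 0.131, adjusted p = 0.0495) was the only such gene among 9 class I MHC genes. Crhr1 was detected on 10 and H2-Q8 on 12 of 45 HDID2 arrays. In the other 25 lists 0 members were called by either adjustment. The striatal projection neuron list had a median of -0.14 (camera adjusted p = 0.313) and the hypothalamic markers one of -0.49 (adjusted p = 0.190). Median and camera direction differed for astrocyte markers, metabotropic glutamate receptors and clock genes, whose medians and means lay below 0. Median and mean differed in sign for the neuropeptide list (0.04 and -0.01) and the class I MHC genes (0.01 and -0.00).

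To ask what the selected lines shared, calls were compared between them. In both lines 14 genes differed from HSNPT in the same direction, 6 higher and 8 lower. Necab1 (1.15 in HDID1 and 1.37 in HDID2) and Pgap4 (1.17 and 1.02) rose by more than 1 in both. The mitochondrial glutamate carrier Slc25a18 (0.97 and 0.85), Evc2 (0.72 and 1.03), 3110070M22Rik (1.05 and 0.50) and Tmub1 (0.28 and 0.32) also rose in both. A second probe of Tmub1 was not called in either line (0.02 and -0.03, unadjusted p = 0.905 and 0.880). Me1 (-1.07 and -1.39), Aebp1 (-0.74 and -0.70), Arv1 (-1.11 and -0.70), Zfp329 (-0.77 and -0.66), Gm8909 (-0.48 and -0.62), the retroviral restriction gene Fv1 (-0.45 and -0.46) and the mitochondrial iron importer Slc25a37 (-0.89 and -0.42) fell in both. Of these, Arv1 lay near background in HDID1, and 3110070M22Rik was detected on 4 of 42 HSNPT, 35 of 46 HDID1 and 13 of 45 HDID2 arrays. Zfp329 was detected on 12 of 46 HDID1 and 9 of 45 HDID2 arrays, and Gm8909 on 19 and Fv1 on 22 of 45 HDID2 arrays. Other kept probes of Fv1 had differences of -0.29 and -0.44 in HDID1 and of -0.21 (unadjusted p = 0.0715) and -0.42 in HDID2. Among arrays with the letter A limma called 4 genes in the same direction in both lines, and among those with the letter B it called 0, with 152 at an unadjusted p below 0.05 in both.

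Another 3 genes differed in both lines in opposite directions, and were named after their values were seen. These were Tmem68 (-2.69 and 1.37), Krt12 (-1.12 and 1.28) and Atm, the kinase of the DNA damage response (0.36 and -0.38). Krt12 had log2 intensities of 9.30 ± 1.79 (SD, n = 42) in HSNPT, 8.17 ± 1.48 (n = 46) in HDID1 and 10.56 ± 0.68 (n = 45) in HDID2. Atm was dim, detected on 6 of 42 HSNPT, 24 of 46 HDID1 and 2 of 45 HDID2 arrays. Over the 116 other arrays 57 genes were shared in direction and 7 were opposite, and Atm was no longer called in HDID2, with an adjusted p of 0.0536.

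**Figure D2:**
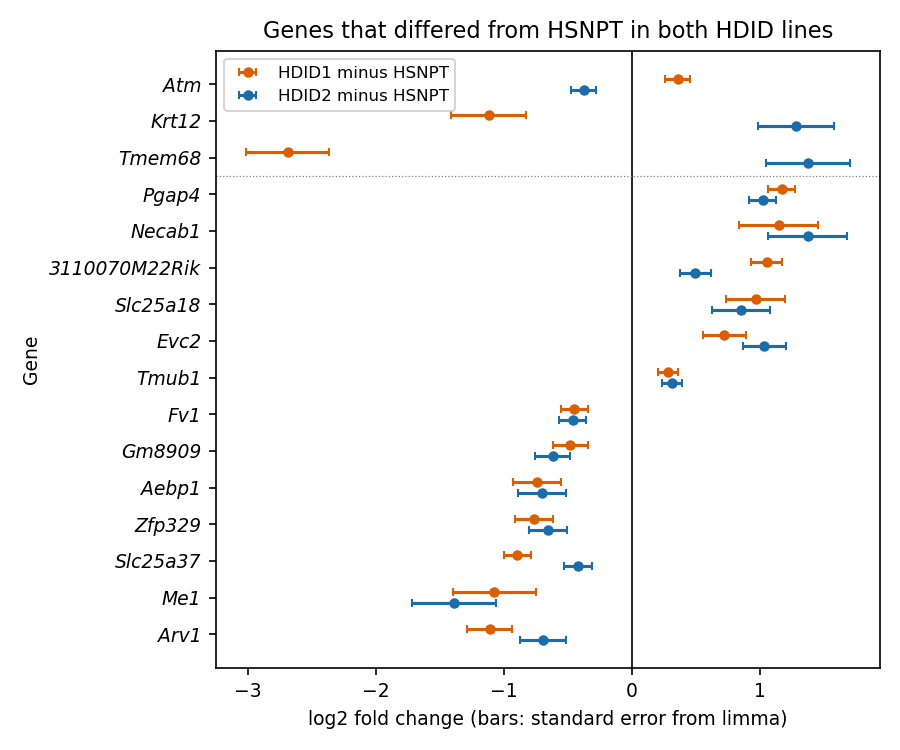
Points are the log2 differences of HDID1 and HDID2 from HSNPT, with limma standard errors as bars, for those genes called in both lines that are named in the text. The 3 genes above the dotted line, Tmem68, Krt12 and Atm, differ in opposite directions, and the genes below it in the same direction.

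Because both comparisons used the same HSNPT mice, the overlap was set beside other values. Independent lists of the same lengths would share 0.821 genes on average. With separate random sets of HSNPT mice for each line, 1.95 genes on average were called in both in the same direction, ranging from 1 to 5 over 20 splits. With these smaller controls 286.6 genes on average were called in HDID1 and 18.65 in HDID2, and 1.35 in both in opposite directions. Across all genes the log2 differences of the lines correlated with r = 0.337, where genes are not independent replicates. Unchanged lines gave a mean r of 0.536 and up to 0.893 in 100 simulations, and separate controls gave -0.0359 on average. The covariance was 0.0124 against 0.0114 simulated, a difference of 0.000959. The sign was shared by 62.3% of genes against 69.2% simulated. Without the 17 arrays r was 0.159 against 0.513 simulated, and the covariance fell short of the simulated one (0.0043 against 0.00514). There the 57 shared genes stood against 14.8 for independent lists of the same lengths. Separate controls gave 13.5 shared in direction on average and 2.8 called in opposite directions. Those came from shorter lists, 632.9 genes on average in HDID1 and 96.5 in HDID2, so 13.5 is not directly comparable with 57 or 14.8.

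The mean of both selected lines was then set against HSNPT. Pgap4 rose by 1.10 (SE 0.0913, limma adjusted p = 5.03e-19), Necab1 by 1.26 (SE 0.268, adjusted p = 0.00452) and Evc2 by 0.88 (SE 0.148, adjusted p = 4.81e-05). Me1 (-1.23, SE 0.285, adjusted p = 0.0114), Slc25a37 (-0.66, SE 0.0942, adjusted p = 3.72e-07), Arc (-0.73, SE 0.172, adjusted p = 0.0141) and H2-Q8 (-0.44, SE 0.114, adjusted p = 0.0371) fell. Limma called 47 genes, 18 higher and 29 lower, and without the 17 arrays 236, 102 higher and 134 lower, which included 46 of the 47. Of the 31 lists 7 passed camera, 1 up and 6 down. Those down were striatal projection neuron genes (0 of 13 called, 6 over the list alone, median -0.32, adjusted p = 3.11e-06), immediate early genes (1 of 11 lower, 2 over the list alone, -0.25, 0.000515), sodium and calcium channels (-0.17, 0.000813), D2 markers (-0.34, 0.00928), potassium channels (-0.12, 0.0202) and endothelial markers (-0.10, 0.0292). The list up was that of myelin markers (0.13, 0.00231). None of these 7 passed camera in both lines. The striatal, immediate early, D2 and channel lists passed in HDID1 alone, and the endothelial and myelin lists in HDID2 alone. The channel, endothelial and myelin lists had 0 called members by either adjustment, and the D2 list 0 over all genes and 3 over the list alone. With an estimated correlation 0 lists passed, and these 7 had adjusted p-values of 0.2135 to 0.221. The count of genes was 25 among arrays with the letter A, 0 among those with the letter B (611 at an unadjusted p below 0.05), 23 among genes detected on 90% of arrays, 9 in females and 4 in males.

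Comparing the selected lines directly asked where lines bred for the same trait had diverged. Among the probes that represented genes, that of Tmem68 differed most, at -4.06 for HDID1 minus HDID2 (SE 0.319, limma adjusted p = 7.03e-21), and 0 of 46 HDID1 arrays lay above the HDID2 mean. Krt12 (-2.40, SE 0.287, adjusted p = 2.49e-10), Gm5148 (-1.59, SE 0.209, adjusted p = 5.49e-09) and Nudt6 (-1.43, SE 0.193, adjusted p = 1.38e-08) were lower in HDID1. Nat8f4 was called lower as well, and no fold is given for it, since it was detected on 0 of 46 HDID1 arrays, 22 of 45 HDID2 arrays and 3 of 42 HSNPT arrays. Tomm22 (1.69, SE 0.213, adjusted p = 1.51e-09), the adhesion gene Lrrtm3 (1.61, SE 0.261, adjusted p = 3.47e-06) and the haemoglobin gene Hbb-b2 (1.65, SE 0.411, adjusted p = 0.00635) were higher in HDID1. These sizes too were set against dim signals, for Tmem68, Gm5148 and Nudt6, detected on 22, 14 and 15 of 46 HDID1 arrays, and for Hbb-b2 and Lrrtm3, detected on 10 and 20 of 45 HDID2 arrays. Of 9645 genes 376 differed, 238 higher and 138 lower in HDID1. Over those 116 arrays 2069 differed, 1106 higher and 963 lower, with 371 of the 376 in the same direction. The count was 107 among arrays with the letter A, 278 among those with the letter B, 203 among genes detected on 90% of arrays and 29 in males.

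Several hypothalamic neuropeptide genes were higher in HDID1 than in HDID2. The oxytocin precursor Oxt (1.68, SE 0.406, limma adjusted p = 0.0045), Gal (1.67, SE 0.325, adjusted p = 0.00019), the vasopressin precursor Avp (1.57, SE 0.447, adjusted p = 0.023) and Trh (0.82, SE 0.223, adjusted p = 0.0149) passed, as 4 of 6 members, and 6 passed when adjusted over the list alone. Avp had log2 intensities of 10.47 ± 2.19 (SD, n = 42) in HSNPT, 11.32 ± 2.06 (n = 46) in HDID1 and 9.78 ± 2.35 (n = 45) in HDID2. The list's median was 1.58 and camera's adjusted p 3.06e-06, against an adjusted p = 0.0919 with an estimated correlation. Striatal projection neuron genes passed camera towards lower values in HDID1, with 0 of 13 called, 6 over the list alone, a median of -0.39 and an adjusted p of 6.26e-07, against an adjusted p = 0.220 with an estimated correlation. Leaving out the 17 arrays, 5 hypothalamic members were higher and 11 striatal members lower.

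**Figure D3:**
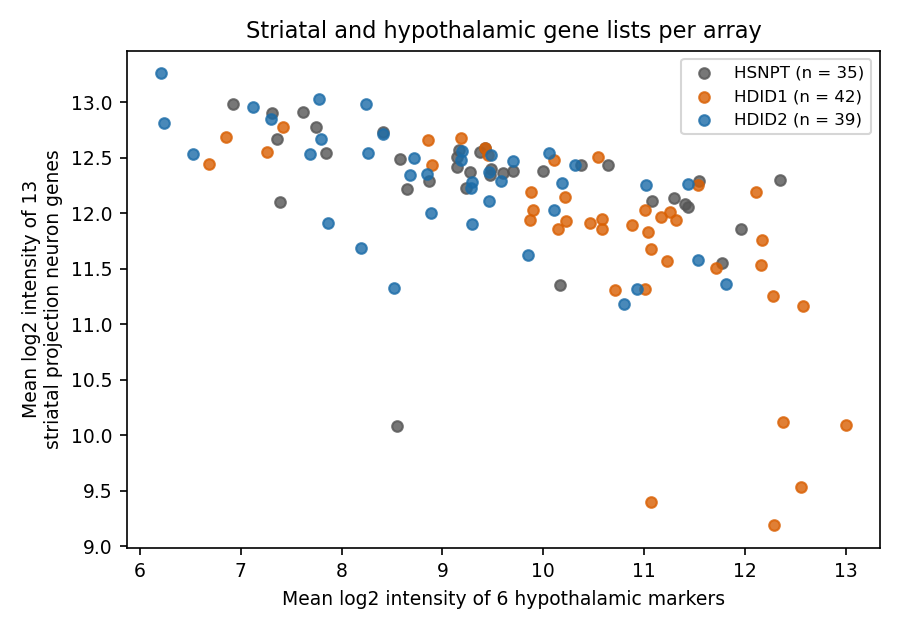
Each point is 1 of the 116 arrays that did not stand apart, with the mean log2 intensity of 6 hypothalamic markers on the x axis and of 13 striatal projection neuron genes on the y axis. HDID1 (42 arrays) had means of 10.55 and 11.75, against 9.49 and 12.30 in HSNPT (35 arrays) and 9.06 and 12.28 in HDID2 (39 arrays).

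A further 6 lists passed camera towards lower values in HDID1 than in HDID2. They were D2 markers (1 of 4 called, 4 over the list alone, median -0.51, adjusted p = 0.00032), cortical excitatory neuron markers (1 of 7, 3, -0.35, 0.00216), potassium channels (3 of 24, 3, -0.08, 0.00637), microglia markers (1 of 11, 2, -0.10, 0.00722), immediate early genes (1 of 11, 1, -0.28, 0.00832) and metabotropic glutamate receptors with scaffolds (0 of 11, 0, -0.12, 0.0158). With an estimated correlation 0 lists passed, and these 6 had adjusted p-values of 0.132 to 0.436. Median and mean lay above 0 while camera's direction was down for cholinergic and interneuron markers, ionotropic glutamate receptors, neuroimmune, oxidative phosphorylation and ribosomal genes and cadherins. Called members were Adora2a (-0.59, SE 0.156), the vesicular glutamate transporter Slc17a7 (-0.99, SE 0.287), Kcnh3 (-0.94, SE 0.229), Trem2 (-0.50, SE 0.0855) and Junb (-0.67, SE 0.178). Hspb1 (0.62, SE 0.132) and Crhr1 (0.52, SE 0.139) were higher in HDID1.

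Males and females were compared over all lines, which also checked the sex labels. The Y-linked genes Eif2s3y (4.51, SE 0.243, limma adjusted p = 6.56e-35), Kdm5d (2.36, SE 0.152, adjusted p = 2.87e-28), Ddx3y (1.19, SE 0.0972, adjusted p = 4.45e-20) and Uty (0.64, SE 0.105, adjusted p = 2.63e-05) were higher in males. Xist, the RNA that silences an X chromosome (-2.81, SE 0.180, adjusted p = 2.5e-28), and the X-linked Kdm6a (-0.30, SE 0.0581, adjusted p = 0.00108) were lower. These 6 were the genes limma called, and 9 were called without the 17 arrays. On 7 of the remaining 116 arrays Eif2s3y went against the label, and on the 4 of them labelled male Xist did too. HDID1 mice 4 and 15 and HSNPT mouse 147, labelled female, had Eif2s3y at 9.98, 10.1 and 7.94. HDID1 mouse 11, HDID2 mouse 100 and HSNPT mice 126 and 158, labelled male, had Eif2s3y between 4.96 and 5.28. The other females lay between 4.85 and 5.98 and the other males between 9.87 and 11.4. Without these 7 arrays limma called 149 genes in HDID1 and 9 in the same direction in both lines.

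**Figure D4:**
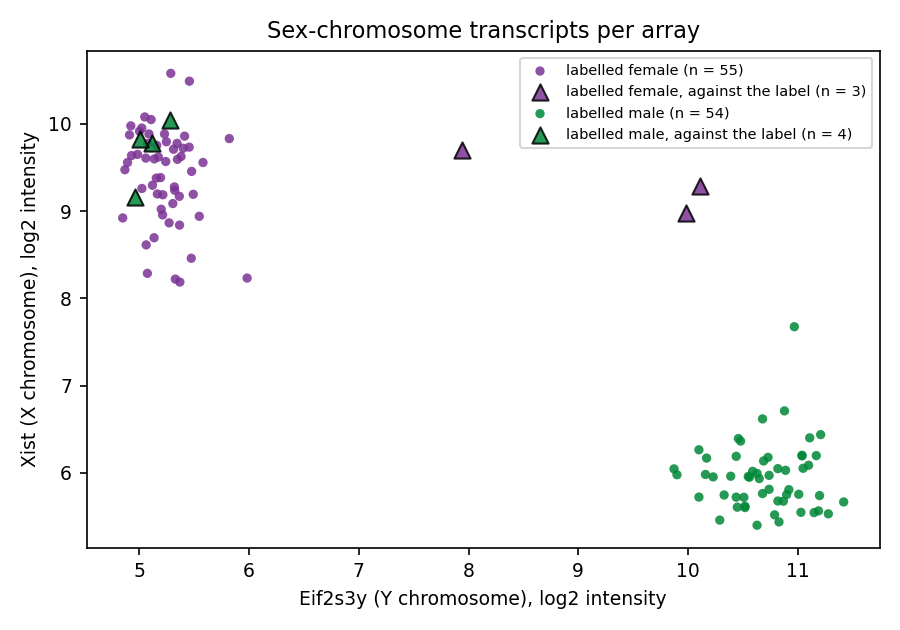
Log2 intensity of Eif2s3y (x axis) and Xist (y axis) on the 116 arrays that did not stand apart. Arrays labelled female (55) and male (54) form separate groups, and 3 arrays labelled female and 4 labelled male lie outside the group of their label.

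No line-by-sex interaction passed limma's test, with 0 genes called and 510 at an unadjusted p below 0.05, and without the 17 arrays again 0, with 644. The lowest p-values were those of Pan3 (0.00139), the serotonin receptor Htr1d (0.00153), Slc22a8 (0.00175), Vcpip1 (0.00277), Arc (0.00336) and Samd4 (0.00368), each with an adjusted p of 0.752. Array weights gave 1243 genes called line by sex interaction, and principal components as terms gave 2439.

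The question in the series title was addressed through the correlation structure within each line. Over the 4000 most variable genes the mean squared correlation was 0.324 in HSNPT, 0.259 in HDID1 and 0.283 in HDID2. The differences from HSNPT, -0.0648 and -0.0409, had permutation p-values of 0.545 and 0.614. Of 9 modules of 30 to 1444 genes, 0 differed in density in either line, with a lowest permutation p of 0.297. Connectivity differed for 0 genes, with 48 in HDID1 and 118 in HDID2 at an unadjusted permutation p below 0.05, and unscaled connectivity also called 0. The median log2 ratio of within-line variance to that of HSNPT was -0.87 in HDID1 (permutation p = 0.208) and 0.12 in HDID2 (p = 0.861).

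Without the 17 arrays the mean squared correlations were lower, at 0.0866 in HSNPT, 0.0818 in HDID1 and 0.0701 in HDID2, and 2 of 10 modules were denser in HDID1. A module of 199 genes led by Ido1, Actn2, Gcnt2, Smpd3 and Gng7 rose in density from 0.0782 to 0.212, and stood at 0.0709 in HDID2. It held 13 of 13 striatal projection neuron genes, 5 of 8 dopamine signalling genes in the network and 5 of 10 immediate early genes. A module of 40 genes led by Resp18, Gpx3, Itih3, Minar2 and Igsf1 rose from 0.0794 to 0.259, stood at 0.188 in HDID2, and held 4 of 6 hypothalamic markers. Each had a permutation p of 0.0099, the smallest the permutations can give, and an adjusted p of 0.0495. The count of 2 modules is not set here against counts from permuted lines. With all arrays permuted lines gave up to 5 called modules in HDID1. The choice to leave out the 17 arrays was made after the data were examined. Between these arrays the striatal list mean had an SD of 0.890 in HDID1, 0.514 in HSNPT and 0.502 in HDID2. For the hypothalamic list mean the SDs were 1.545, 1.475 and 1.411. Whether the tissue content of the dissections raised these densities was not tested. In HDID2 0 modules differed, and connectivity differed for 0 genes in either line.

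Called genes were not spread evenly over the chromosomes in HDID1. They were in excess on chromosome 4 (26 of 507 genes, odds ratio 1.97, Fisher's exact adjusted p = 0.0158), chromosome 9 (22 of 457, 1.82, adjusted p = 0.0422) and chromosome 13 (17 of 286, 2.27, adjusted p = 0.0158). Tmem68, Pgap4, Necab1, Casp9, Ccl27a, Dnajb5 and Fv1 were among those on chromosome 4, and Paip1, 3110070M22Rik and 4833420G17Rik among those on 13. Fewer than by chance lay on chromosome 2 (6 of 665, adjusted p = 0.0144), chromosome 10 (3 of 405, adjusted p = 0.0204) and chromosome 16 (0 of 254, adjusted p = 0.0144). Fisher's test takes genes as independent. In HDID1, 56 of 265 called genes had a called neighbour, against a median of 28 in random sets, so the p-values by chromosome may be too small. With every kept probe tested on its own, chromosome 9 (adjusted p = 0.0585) and chromosome 10 (0.102) no longer passed. In HDID2 no chromosome passed with 1 probe per gene, chromosome 4 holding 9 of 507 genes (odds ratio 3.21, adjusted p = 0.0835). With every kept probe chromosome 4 passed in HDID2 (10 of 717 probes, odds ratio 3.41, Fisher's exact adjusted p = 0.0363). Without the 17 arrays the excess in HDID1 was on chromosome 13 alone (61 of 286, adjusted p = 0.0142), chromosomes 2, 10 and 16 no longer held fewer than by chance (adjusted p = 0.660, 0.537 and 0.537), and chromosome 4 passed in HDID2 (23 of 507, adjusted p = 0.0366) and for the genes shared by both lines (10 of 507, adjusted p = 0.0304).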

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

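The tests of the arrays standing apart, of RNA from both sexes, and of other splits of the arrays for gene counts, for the correlation between lines, for the interaction and for the network were chosen after the results they bear on were seen.

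Between the lines, 3 genes were called in opposite directions against HSNPT. They were picked by those calls, so limma's HDID1 minus HDID2 values from the same arrays restate the choice and are no further evidence. Each line was 1 population, so drift is not told apart from selection. Tmem68 differed by -4.06 (SE 0.319, adjusted p = 7.03e-21), with 3 of 46 HDID1 and 41 of 45 HDID2 arrays above the HSNPT mean. Krt12 differed by -2.40 (SE 0.287, adjusted p = 2.49e-10), with 15 and 45 arrays above it. Atm differed by 0.73 (SE 0.0968, adjusted p = 6.13e-09), with 37 and 11 arrays above it, and was dim. The hypothalamic markers also differed between the lines, with a median HDID1 minus HDID2 difference of 1.58, 4 of 6 members called and a camera adjusted p of 3.06e-06, but an adjusted p = 0.0919 with an estimated correlation.

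Several genes of striatal projection neurons were lower in HDID1 than in HSNPT, with 6 of 13 called, a median of -0.52 and a camera adjusted p of 2.67e-09, but an adjusted p = 0.120 with an estimated correlation. The arrays standing apart were not the cause, since 12 members were called lower without them. The fall was uneven over the HDID1 arrays, with striatal list means of 9.19 to 10.12 in mice 1, 35, 39, 43 and 45. Tissue of the hypothalamus in the dissections may account for part of it. Over the 116 arrays that did not stand apart, with the mean of the hypothalamic markers as a term, the median went from -0.59 to -0.30. Of the median 51.5% was left (bootstrap SD 16.2), and that test leaves the explanation open. Of that list, the genes with the brightest probes were Oxt (10.92 in HSNPT, 11.73 in HDID1) and Avp (10.47 and 11.32). Neither was called in HDID1 (limma adjusted p = 0.3725 and 0.3859), and levels of different probes are not directly comparable. Of the 6 markers 5 were detected on most HSNPT arrays, and 1 is also in another list. A lower share of striatal neurons was predicted to raise the markers of other cell types alike. Over the 77 HSNPT and HDID1 arrays that did not stand apart, astrocyte (0.03) and myelin markers (0.07) shifted up. Microglia (-0.12), endothelial (-0.12) and cholinergic markers (-0.10) shifted down, and the shifts were not shown to differ (permutation p = 0.0943). Cholinergic neurons are also found in the striatum, so that list need not rise. The test therefore cannot decide, and a lower share stays open, as does an untested change of expression in HDID1 itself.

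Single genes differed between the lines by large amounts. For called genes with other kept probes, taken as a set, a sequence variant under the probe as the whole cause was argued against. Of 91 such probes 56 differed the same way at an unadjusted p below 0.05, 61.5% (95% interval 51.5 to 70.9 when the 63 genes were resampled). Among genes not called the share was 10.7% for HDID1 and 2.49% for HDID2. Only 7 of these probes were of genes called with an absolute log2 difference over 1, several of them of Actl6b, and 7 differed the same way. Whether the probes of a gene cover different bases was not checked, so a variant shared by probes is not excluded. Tmem68, Krt12, Tomm22 and Cops8 had no other kept probe, so the test does not cover them. Agreement was in direction, and sizes differed between probes of Nln and of Actl6b. A variant stays possible for single genes. Chromosome segments that differ between the lines may contribute, since 60 called genes had a called neighbour, 56 of 265 in HDID1 against a median of 28 in 2000 random sets (p = 0.0009995) but 4 of 58 in HDID2 against 0 (p = 0.146). Without the arrays standing apart the counts, again set against random sets, were 632 against 592 in HDID1 (p = 0.02499) and 44 against 18 in HDID2 (p = 0.0004998). Segments cannot be told apart from neighbours regulated together, since genotypes were not used.

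On 7 arrays Eif2s3y went against the sex label, and on the 4 of them labelled male Xist did too. A wrong line label as well was argued against by 6 of the 7 lying nearest to their own line, against 108 of 109 other arrays, the exception being HDID2 mouse 100, nearest to HSNPT. RNA of both sexes on the array may explain the 3 arrays labelled female, where Eif2s3y (7.94 to 10.1) and Xist (8.98 to 9.70) were both high. It was argued against for the arrays labelled male, 4 of which had Eif2s3y in the female range and Xist between 9.17 and 10.04, the levels of a female. No biological explanation was tested.

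Other splits of the arrays into groups of the same sizes, drawn 100 times with the real split included, tested the counts against chance. Chance was argued against for HDID1 against HSNPT (269 genes, highest other split 0), reached by 1 split, the real one. The splits do not test the genes shared in direction (14, highest other 0, reached by 1 split), since no other split called a gene in HDID1 and none could then be shared. Counts reached by 2 splits, the real one included, were those of HDID2 against HSNPT (58, highest 534) and the mean (47, highest 2386). The same held for HDID1 against HDID2 (376, highest 1341) and sex (6, highest 2744). Chance is unlikely for these counts but not excluded, since another split called more genes. The splits of the lines kept sex but not the title letter or the array runs, and mice are not replicates of the selection. The splits with several times the real count point to a structure of the samples other than line, and without the arrays standing apart the highest others were 1, 244, 1, 31 and 1054 for HDID1, HDID2, the mean, HDID1 against HDID2 and sex.

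Chance was not excluded for the correlation between the lines (r = 0.337, reached by 71 splits, highest other 0.942). For the number of gene lists past camera, 12 of 100 splits did as well in HDID1 (6 lists, highest other 12), 30 in HDID2 (4, highest 10), 9 for the mean (7, highest 10) and 5 for HDID1 against HDID2 (8, highest 9), so chance was not excluded there. Nor was it excluded for 2 measures of the network. The mean squared correlation was reached by 54 splits in HDID1 (-0.0648, highest other 0.286) and 61 in HDID2 (-0.0409, highest 0.297), and the variance ratio by 21 (-0.87, highest 2.00) and 86 (0.12, highest 1.72). A count of 0 is met by any split, so the splits say nothing about the interaction (0 genes, met by 100 splits, highest other 3838), modules (0 changed in each line, highest 5 and 3) or connectivity (0 genes in each line, highest 353 and 362).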

How the results depend on the processing

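The settings without the arrays standing apart, with array runs as a term, without the arrays whose sex transcripts went against the label, with the letter B alone and with the unlabelled sample were chosen after the data were examined.

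Of the counts, list, network and chromosome values under alternatives, 135 stayed within the limits for their kind, 76 moved further and 5 changed sign. Some of the 135 say little about stability. The mean contrast under only the groups compared was that of the main fit and could not move. The fold threshold removed no called gene from the 3 contrasts against HSNPT. The limit was 1.5 times the reported count, or 1 SD for the correlation between the lines. For the mean squared correlation and the variance ratio it was only the same sign and the same side of the threshold. Counts are given in the order HDID1, HDID2 and mean of the lines against HSNPT, HDID1 against HDID2, shared in direction, sex, interaction, and values not named stayed within those limits. The cause was not tested except where stated.

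Some settings raised the counts. Without the arrays standing apart limma called 1338, 215, 236, 2069 and 57 genes. Array runs as a term, without HDID2 mouse 102, gave 1405, 201, 289, 1477, 61 and 10. Array weights gave 2264, 386, 706, 2727, 129 and 15 genes, and 1243 genes called line by sex interaction. The first 2 residual principal components as terms gave 3251, 856, 1666, 3206, 331, 577 and 2439. These components are orthogonal to line and sex by construction, so the differences stayed and only their errors shrank.

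Other settings lowered counts. Females alone gave 84, 9 and 9 genes, and 1 shared. Males alone gave 16, 8, 4 and 29, and 1 shared. Arrays with the letter A gave 84, 30, 25, 107 and 4 shared. The 22 arrays with the letter B gave 3, 4 and 0 genes (611 for the mean at an unadjusted p below 0.05), 0 shared (152) and 3 by sex. With 4 HSNPT arrays, all of males, the interaction could not be fitted there. Genes detected on 90% of arrays gave 160, 6, 23 and 203, 1 shared and 2 by sex. Fitting only the groups compared gave 24 in HDID2 and 7 shared, but 388 in HDID1. Leaving out the 7 arrays with sex transcripts against the label gave 149 in HDID1 and 9 shared.

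No detection filter gave 37 in HDID2 and 7 shared, and more genes entered the adjustment. The title letter as a term gave 138 in HDID1. Every kept probe tested on its own gave 10 by sex and 1 chromosome in HDID2. Over all alternatives the counts ranged from 3 to 3251 in HDID1, 4 to 856 in HDID2, 0 to 1666 for the mean, 29 to 3206 between lines, 0 to 331 shared, 2 to 577 by sex and 0 to 2439 for the interaction. The correlation between the lines ranged from 0.159 to 0.542, within its bootstrap SD of 0.227.

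With an estimated correlation 0 lists passed in each of the 4 contrasts. By fry 1 list passed in HDID2, 3 for the mean and 2 between the lines, and with principal components as terms 2 in HDID2 and 4 for the mean. Without the arrays standing apart 10 passed in HDID1.

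The mean squared correlation of HDID1 minus HSNPT changed sign to 0.00275 with 2 principal components removed, and that of HDID2 to 0.0303 among arrays with the letter A. The variance ratio of HDID2 changed sign to -0.25 with the letter A, -0.24 with components removed and -0.086 without the arrays standing apart. None of these passed its test. Without the arrays standing apart the variance ratio of HDID1 went from -0.874 to -0.218 with the sign kept. Its mean squared correlation difference went from -0.0648 to -0.00478. Modules called in HDID1 numbered 3 with components removed and 2 without the arrays standing apart, and Spearman correlation called 1 gene by connectivity in each line. Chromosomes in excess without the arrays standing apart numbered 1 in HDID1, 1 in HDID2 and 1 for shared genes.

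For 263 gene results, 91 of them called, 4735 values under alternatives gave 4220 on the same side of the threshold, 146 of the uncalled ones with the other sign, while in 357 a call was lost and in 152 a call was gained. Dnajb1 in HDID1, uncalled at 0.05, changed sign under array weights, to -0.12, and was called there. Called values changed sign among arrays with the letter B, uncalled there, for Gm8909 (0.0250), Junb (0.0150) and Zfp329 (0.0790) in HDID1 and for Slc25a37 (0.0322) and Zfp329 (0.126) in HDID2. Most losses came with the letter B alone (74), males alone (66), females alone (52) and arrays with the letter A (43).

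The slide as a block was not run, since the sources used here give no slide. No paired analysis was possible because each mouse belonged to 1 line and the sample numbers in the labels are not shared between lines. Signal over background limits dim genes such as Atm, and limma recovered 6% of simulated changes of 0.25 with all arrays against 50% without those standing apart.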

Other observations

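The within-line correlations, the overlap of modules with gene lists, the nearest-line counts and the values of the unlabelled sample were chosen after the data were examined.

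Without the arrays standing apart, some modules held more members of a gene list than by chance. A module of 60 genes led by Wfdc2, Kl, Calml4, Otx2 and Mlf1 held 10 of 10 choroid plexus markers (Fisher's exact adjusted p = 7.65e-17 over 290 tests). A module of 35 genes led by Cckbr, Stx1a, Vxn, Tbr1 and Fhl2 held 3 of 7 cortical excitatory neuron markers (adjusted p = 0.00122). The module with 13 of 13 striatal projection neuron genes (adjusted p = 1.13e-15) also held 5 of 8 dopamine signalling genes (0.00104), 4 of 5 D1 markers (0.00138), 5 of 10 immediate early genes (0.00247) and 3 of 4 D2 markers (0.017). The module with 4 of 6 hypothalamic markers had an adjusted p of 1.23e-05. The striatal, dopamine, D1, D2 and hypothalamic lists share members with other lists. The choroid plexus, cortical and immediate early lists do not.

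Arrays with more hypothalamic neuropeptide RNA had less striatal RNA within each line, over the 116 arrays that did not stand apart and with sex removed. Pearson's r between the list means was -0.363 in HSNPT (n = 35, permutation p = 0.0288), -0.666 in HDID1 (n = 42, p = 5e-05) and -0.629 in HDID2 (n = 39, p = 5e-05), where 5e-05 is the smallest the permutations can give. Adjusted over these 3 relations the p-values were 0.0288, 7.5e-05 and 7.5e-05. Spearman's rho was -0.584 (p = 4e-04), -0.789 (p = 5e-05) and -0.608 (p = 2e-04). Without the 2 arrays farthest from the median hypothalamic mean, r was -0.356, -0.674 and -0.568.

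Among genes outside the lists, Samd4 rose in HDID2 (0.88, SE 0.184, limma adjusted p = 0.00361), with 32 of 45 arrays above the HSNPT mean. It was detected on 5 of 42 HSNPT, 4 of 46 HDID1 and 28 of 45 HDID2 arrays, and differed between the lines by -1.10 (adjusted p = 4.03e-06), with 1 of 46 HDID1 arrays above the HDID2 mean. Tmem68 varied more between HSNPT mice (SD 2.24) than within HDID1 (1.12) or HDID2 (1.04).

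Of 109 arrays whose sex transcripts followed the label, 108 lay nearest to the centroid of their own line, and HSNPT mouse 146 lay nearest to HDID2. The sample without a sex label had, in the authors' value table, a log2 intensity of Eif2s3y of 8.07, where females ranged from 7.73 to 8.30 and males from 10.2 to 11.6. Its Xist value was 9.09, where females ranged from 9.11 to 10.8 and males from 8.11 to 8.86. Its mean correlation with 116 arrays was 0.948.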
